A study of Mus musculus with 12 samples.

How the data were processed

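The data were 4 lists deposited by the authors for 12 ChIP-seq samples of mouse ESCs and iPSCs. Per the submitters' processing notes, Bowtie2, SAMtools, bedtools and MACS2 were named, with mm10 as the genome build, without versions or the role of each tool. How the 2 replicates of a group were combined is not given in the sources used here. Lists were tied to groups by the names the authors gave them, and samples to groups by their titles. The labels give the ESC and iPSC replicates as biological replicates, but no list holds values per replicate, so no test across replicates was possible.

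The deposited ESC lists have 10 columns without a header and hold 10 kb bins. The last column was read as H3K27ac signal, because the authors deposited these lists for that mark, and a bin without signal holds the smallest number a computer stores. The normalization of the deposited signal is not given in the sources used here, nor whether both times were scaled to each other, so changes in value were read relative to the median of all bins valued at both times. Values as deposited are printed for some genes and are not comparable between the times without that scaling. Which bins have a value at 1 time only also depends on the unknown scaling and threshold. The fourth column is a whole number of 1 or more, called the bin score, whose meaning the deposited lists do not state. The 5 columns between hold marks of 0, 1 or 2 that were equal in both lists on all 41942 shared bins and entered the comparisons only in 1 alternative that kept unmarked bins. The KLF4 share, genes and relative values of marked bins are described in the closing section. The reading of the last column was checked against the iPSC peaks: 73.6% of 0 h bins with a value and 3.16% of bins without one held an iPSC H3K27ac peak. About 31% of valued bins (30.8% at 0 h and 31.1% at 24 h) had the value of the next bin, which leaves 19129 distinct runs among 22739 bins valued at both times. Neighbouring bins are therefore not independent, which is why errors were taken over chromosomes. The deposited iPSC lists hold positions only, with no height or score, and peak width was used where a ranking was needed.

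Gene positions came from RefSeq for GRCm38.p6, the same primary assembly as mm10. That table gave no strand and no sequence was used, so a promoter could not be placed. The planned promoter class became a bin or peak within 2 kb of either end of a protein-coding gene, and bins and peaks were assigned to the gene with the nearest end within 100 kb. Motifs were not analysed here. All bins have 1 width, so the planned deciles of width were void and gene-end class alone formed the groups. The width deciles had been planned because narrow or weak peaks are lost more often by chance. Gene-end class alone does not hold the level fixed, and deciles of the value were added to it in 1 alternative. A mutual overlap of 50% changes nothing between bins of 1 grid and was not run there.

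Overlap was 1 bp or more, with exact (Clopper-Pearson) binomial intervals at 95% for counting error only. Chance overlap came from 1000 circular shifts of a list within chromosomes, for which 0.001 is the smallest p. Odds ratios were Mantel-Haenszel estimates with a jackknife SE over 20 chromosomes. Relative values per gene are means over the bins valued at both times that a gene and 10 kb on each side touch. Bins valued at 1 time only do not enter these means or the list medians. A gene with no bin valued at both times, such as Axin2, has no relative value. Gene lists were 15 lists with 274 entries and 262 distinct genes, all of them in the reference, fixed before the data were examined. They were tested as planned with two-sided Fisher exact tests against all other genes with an ESC bin assigned. H3K27ac pieces 10 kb or less apart were joined to clusters, ranked by covered length, and the largest 500 taken.

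Several tests were added after the data had been seen: the value difference and the score difference between bins with and without KLF4 within deciles of level or total score, the count of bins valued at 1 time only, the percentile of list medians among 10000 random lists of measured genes in the same level deciles, and the naming of genes with the lowest and highest relative values or score differences. Genes named by the rule fixed before the data were examined were 9 pluripotency genes, the 10 genes with the largest excess of each ESC class, the 10 with the most KLF4 peaks and with the most 0 h-only bins holding KLF4, the 10 with the largest excess in iPSCs or ESCs, up to 4 members per list by KLF4 peaks, and the 5 largest clusters per list. Some items that these rules name are not reported here. Alternatives changed the overlap rule, merging, list length, chromosomes, groups, distances, joining distance and the bins used.

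The overlap, odds ratio, value difference, score difference and gene-list statistics were tested on simulated data, and the cluster shares and the rankings of genes were not. Log2 ratios were shuffled over bins, and absences and scores were drawn independently for each bin. Such draws hold no runs of equal neighbouring values and no link between ratio and level. They therefore do not test how the statistics behave under those features of the data. A value difference of -0.3 log2 placed at the KLF4 bins among 22739 bins was recovered as -0.30 on average over 20 draws, and the interval held the true value in 19 of 20. A log odds ratio of 0.7 over 26812 bins was recovered as 0.71, and held in 18 of 20. A score difference of -5 percentage points over 54825 bins was recovered as -5.01. Of 14 unchanged simulated lists, 1 fell outside the central 95% of random lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Input libraries were not used here.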

Results

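Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active enhancers and promoters, and binding of KLF4, a zinc-finger transcription factor of the pluripotency network. The 12 mouse samples fell into 7 groups. V6.5 embryonic stem cells (ESCs) carried a doxycycline-inducible Cas9 with guides, which the labels give as against Klf4 alone or against Klf2, Klf4 and Klf5 together, and H3K27ac was measured in 2 replicates before induction (0 h) and 2 replicates after 24 h. Induced pluripotent stem cells (iPSCs), made by reprogramming somatic cells, were measured in 2 replicates for KLF4 and 2 for H3K27ac. The inputs were 2 ESC libraries, 1 library for iPSC KLF4 and 1 for iPSC H3K27ac. All cells were grown in 2i, a medium with inhibitors that hold mouse cells in the naive state. The titles of the 24 h samples carry both the name TKO, read here as knockout of the 3 genes, and the words KLF4 KO, and the design speaks of a KLF knockout, so which genes were targeted is not settled by the labels.

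Each ChIP group was represented by 1 deposited list, so no replicate error could be computed and read depth was unknown. The 0 h ESC list held 49460 bins of 10 kb, of which 26812 carried an H3K27ac value, with a median of 4.65. The 24 h list held 47307 bins, of which 25611 carried a value, with a median of 4.05. The iPSC lists held 55466 H3K27ac peaks with a median width of 405 bp and 21563 KLF4 peaks with a median width of 262 bp. Coordinates are those of mm10. Intervals on shares are 95% exact binomial intervals for counting error, standard errors (SE) are from a jackknife over 20 chromosomes, and both describe these lists rather than the spread between cultures.

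The first comparison asked how H3K27ac in ESCs differed 24 h after induction of the knockout. At the genes named as targets, the relative log2 value of 24 h over 0 h was -0.12 at Klf2 (chromosome 8, 72319062 to 72321654), -0.05 at Klf4 (chromosome 4, 55527137 to 55532475) and 0.43 at Klf5 (chromosome 14, 99298691 to 99313412). The SD over bins was 0.46 for the 3 bins of Klf4 and 0.32 for the 5 bins of Klf5. Klf4 changed sign, to 0.05, with 25 kb flanks in place of 10 kb. Acetylation around a gene does not report whether its coding sequence was cut, so these values are no check of the knockout. Relative values are set against the median of the 22739 bins with a value at both times, which was -0.23 log2, or a ratio of 0.854. Among other regulators of pluripotency, the relative value was -0.12 at Nanog, -0.21 at Pou5f1 (encoding OCT4), -0.06 at Sox2, -0.06 at Esrrb, -0.22 at Tbx3 and -0.18 at Zfp42 (also known as Rex1). The bins of Klf2, Nanog, Pou5f1, Tbx3 and Zfp42 with a value at both times shared 1 value per time, so they give no spread. The SD over 10 bins of Esrrb was 0.17.

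The H3K27ac domains were largely the same at both times. Of the 0 h bins with a value, 84.8% (84.4 to 85.2) also had one at 24 h, and 88.8% (88.4 to 89.2) of the 24 h bins had one at 0 h, against means of 10.4% and 10.9% in 1000 circular shifts of a list (circular-shift permutation test, p = 0.001, the smallest the shifts can give). The 0 h list held 4073 bins without a 24 h value, of which 2309 were absent from the 24 h list and 1764 were listed there without a value. The 24 h list held 2872 bins without a 0 h value, of which 1378 were absent from the 0 h list and 1494 were listed without a value. A bin absent from a list has no value for that reason, and was not shown to lack acetylation.

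**Figure D1:**
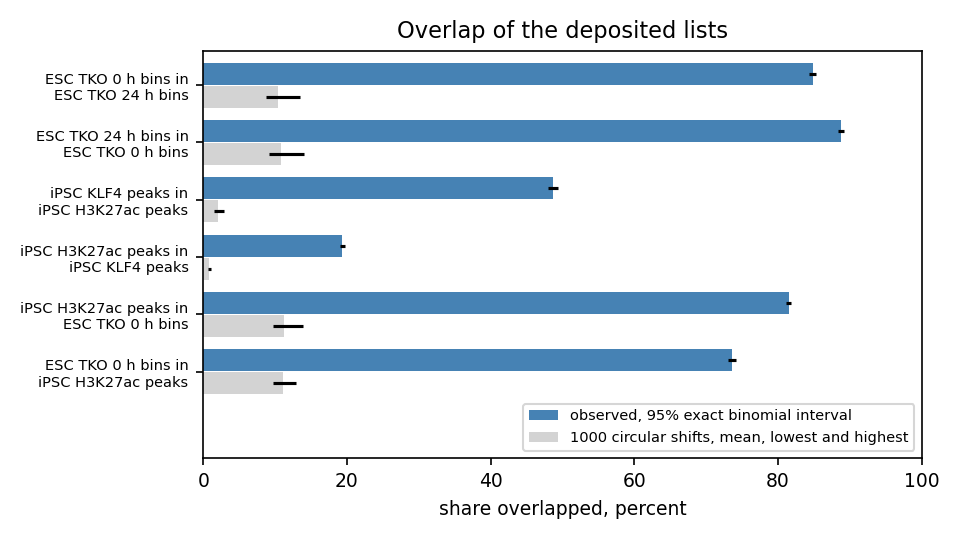
Share of bins or peaks of each list overlapped by another list (horizontal axis, percent), with 95% exact binomial intervals in blue and the mean, lowest and highest of 1000 circular shifts in grey. All 6 observed shares lie above the highest shifted share, from 19.3% for iPSC H3K27ac peaks with KLF4 to 88.8% for 24 h bins with a 0 h value.

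Genes with the largest excess of 0 h-only bins included D16Ertd472e and Dnajc5b with 6 such bins each and no 24 h-only bin, and Dock5, Msc, Nav1, Pitpnc1 and Rnf2 with 5 each. Around Dnajc5b (chromosome 3, 19508591 to 19610862) the highest 0 h value was 11.0, and around Msc (chromosome 1, 14753344 to 14756089), a basic helix-loop-helix repressor gene, it was 11.4. No bin around either gene had a value at 24 h. Igsf3 had 5 0 h-only bins and 1 24 h-only bin, Ccdc60 and Diaph2 had 4 and none. Gja1, Myof and Ptpn3 also had 4 and none, and were left out by the cut at 10 genes. In the other direction, Gadd45g, a stress-response gene, and Smarcc1, a subunit of the BAF remodelling complex, each had 5 24 h-only bins and no 0 h-only bin. Kif15 had 5 and 1, and Atg7, Chst11, Mad1l1, Nav2, Ptpn14, Pum2 and Sfi1 had 4 and none. The highest value around Chst11 (chromosome 10, 82984440 to 83195904) was 5.10 at 0 h and 7.73 at 24 h.

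Among the 4932 genes with at least 3 bins valued at both times, the SD of the relative value over genes was 0.22. The 10 lowest values were at Pramel6 (-0.98), Msln (-0.98), Adad2 (-0.94), Fam189a1 (-0.91), Pramel7 (-0.90), Cfap206 (-0.86), Mob3c (-0.86), the shared bins of Saa3 and Saal1 (-0.84) and Spic (-0.83). Pramel6 and Pramel7 are neighbouring genes of the PRAME family on chromosome 2 and share some of their bins, so their values are not independent. The highest value was 13.0 at 0 h and 5.65 at 24 h for Pramel6 and 13.3 and 6.48 for Pramel7. The highest values were at Fgfr2 (1.03), a receptor for fibroblast growth factors, Igsf9b (1.01), Slc22a23 (0.86), Serinc5 (0.84), the shared bins of Rab26 and Traf7 (0.81), Sulf1 (0.81), Rps6kl1 (0.79), Tnfrsf13c (0.76) and Prmt8 (0.75). The SD over bins was 0.02 for Pramel6, 0.11 for Pramel7 and 0.56 for Fgfr2, and reached 0.85 for Adad2 and 1.23 for Rab26. This ranking was added after the data had been seen, and single genes were not tested.

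The second comparison asked whether H3K27ac that differed between the times lay where KLF4 bound in iPSCs. Bins with a KLF4 peak had higher H3K27ac than other bins at both times, with medians of 5.51 and 4.21 at 0 h (ratio 1.31) and 4.51 and 3.84 at 24 h (ratio 1.18). Of 10177 0 h bins with KLF4, 13.0% had no 24 h value, against 16.5% of 16635 bins without KLF4, and the odds ratio within gene-end groups was 0.79 (0.73 to 0.85). Of 9296 24 h bins with KLF4, 4.72% had no 0 h value, against 14.9% of 16315 others, and the odds ratio was 0.30 (0.27 to 0.34). Neither odds ratio is adjusted for the higher H3K27ac value of KLF4 bins. The 0 h odds ratio turned to 1.15 (1.04 to 1.26) within gene-end groups and deciles of the H3K27ac value, so its direction depends on that adjustment. It turned to 1.07 (0.98 to 1.18) when neighbouring 24 h bins within 1 kb counted as present. With both H3K27ac lists cut to bins above their median it was 1.13 (1.04 to 1.23). There a bin below the 24 h median counted as absent even with a 24 h value, so this odds ratio measures something else. The 24 h odds ratio stayed below 1 under each of the 10 alternatives run for it.

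Of the 1759 KLF4 bins valued at 1 time only, 1320 (75.0%) had their value at 0 h and 439 at 24 h. Of the 5186 such bins without KLF4, 2753 (53.1%) had it at 0 h, for an odds ratio of 2.61 (2.34 to 2.91). Genes with the most 0 h-only bins that held KLF4 were Ccdc60 and Igsf3 with 4 each, followed by Dnajc5b, Gja1 (connexin 43), Myof, Ndrg1 and Ptpn3 with 3 each. The genes 1600014C23Rik, 1700001O22Rik and Ajap1 had 2 each. In the bins valued at both times, the log2 of the 24 h over the 0 h value was lower in the 8857 bins with KLF4 than in the 13882 others at equal level and gene-end class, with a difference of -0.17 (SE 0.007). The shifted KLF4 lists gave -0.04 to 0.03 (circular-shift permutation test, p = 0.001, the smallest they can give). The difference was -0.11 at equal 0 h value in place of the mean level, and -0.12 near gene ends. The median relative value was 0.06 with no KLF4 peak, -0.07 with 1, -0.11 with 2 and -0.12 with 3 or more. These medians are not adjusted for level, and the median 0 h value of the same bins was 4.41, 5.55, 6.35 and 7.33. Both this value difference and the count of bins valued at 1 time only were tests chosen after the data had been seen.

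**Figure D2:**
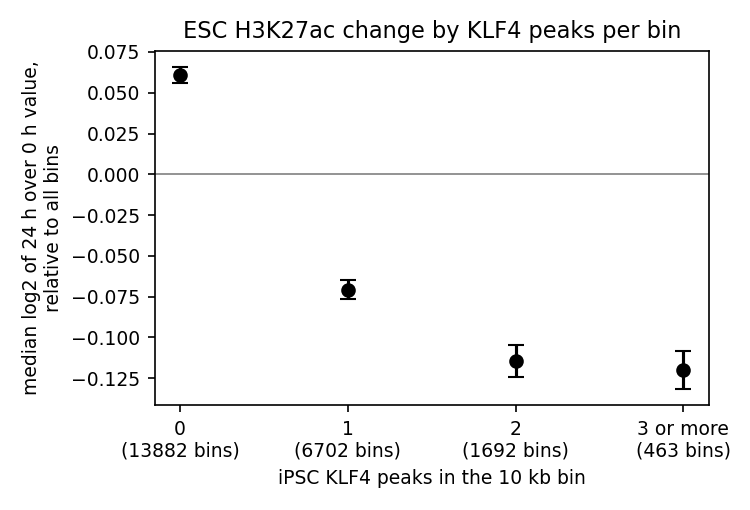
Median log2 of the 24 h over the 0 h H3K27ac value of ESC bins, relative to all 22739 bins valued at both times (vertical axis), by the number of iPSC KLF4 peaks in the 10 kb bin (horizontal axis). Bars are SEs over 20 chromosomes, and the median, not adjusted for level, goes from 0.06 with no peak to -0.12 with 3 or more.

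Each ESC bin also carried an unlabelled whole number, called the bin score here, which summed to 186496 at 0 h and 168512 at 24 h, a ratio of 0.904. In bins without KLF4 the 24 h list held 48.4% of the summed score of both times (SE 0.25), and in bins with 1 KLF4 peak 45.9% (SE 0.19). Around Esrrb, which encodes an orphan nuclear receptor, the summed score was 159 at 0 h and 140 at 24 h, and around Klf5 it was 54 and 65. At equal total score and gene-end class, bins with KLF4 had a lower 24 h share, with a difference of -4.81 percentage points (SE 0.36), against -1.42 to 1.90 in the shifted lists (circular-shift permutation test, p = 0.001). Without these groups the difference was -2.62 (SE 0.21), and within them it was -2.52 in bins listed at both times and -2.19 in bins valued at both. This test, too, was chosen after the data had been seen.

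**Figure D3:**
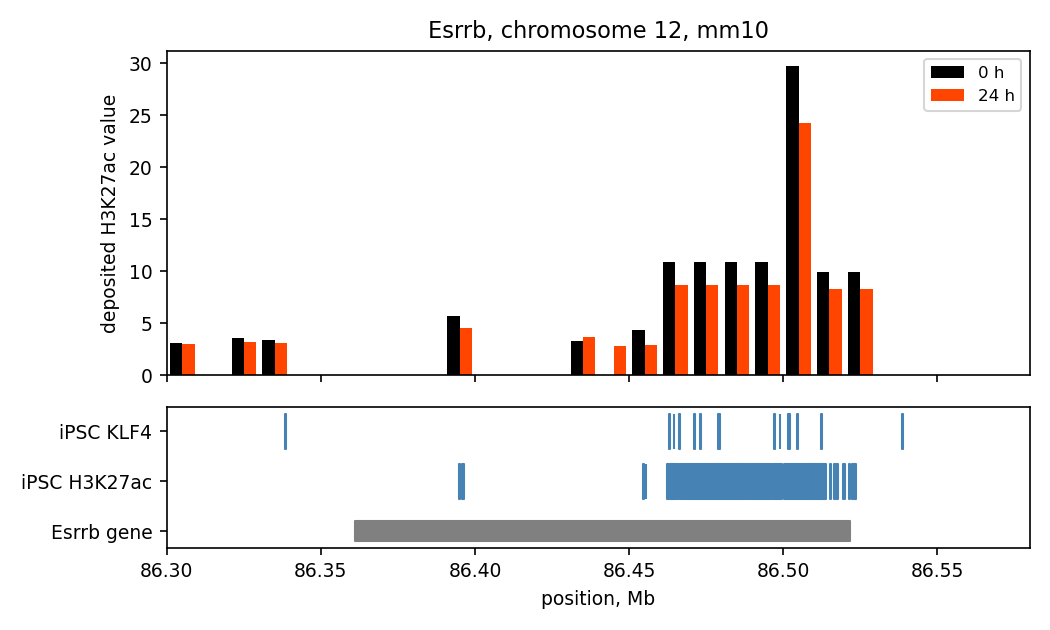
Map of Esrrb on chromosome 12, 86300001 to 86580000 (mm10, horizontal axis in Mb), with the deposited H3K27ac value of each ESC bin (vertical axis) at 0 h in black and at 24 h in orange, and iPSC KLF4 peaks, iPSC H3K27ac peaks and the gene below. The highest bin was 29.7 at 0 h and 24.2 at 24 h as deposited, while all bins had a median ratio of 0.854, and the relative value around Esrrb was -0.06 (SD 0.17 over 10 bins).

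The third comparison asked where KLF4 and H3K27ac met in iPSCs. Of the KLF4 peaks, 48.7% (48.0 to 49.4) overlapped an H3K27ac peak, and 19.3% (19.0 to 19.7) of the H3K27ac peaks overlapped a KLF4 peak, against at most 2.95% and 1.14% in the shifts (circular-shift permutation test, p = 0.001). Only 4.46% of KLF4 peaks met an H3K27ac peak, and 1.73% of H3K27ac peaks a KLF4 peak, when each had to cover 50% of the other. Near and away from gene ends, overlapping KLF4 peaks had median widths of 319 and 297 bp, and overlapping H3K27ac peaks 839 and 895 bp. An overlapping KLF4 peak of median width is too narrow to cover 50% of such an H3K27ac peak. Widths therefore limit these 2 shares. The share of H3K27ac peaks with KLF4 was 36.1% with lists of equal length, 32.4% with a KLF4 peak within 1 kb and 30.1% with near peaks merged. The share was 57.3% (56.1 to 58.4) for KLF4 peaks near a gene end and 43.8% (43.0 to 44.6) away from gene ends. Genes with the most KLF4 peaks were Gas8 with 57, Rhou with 34, Gm40363 with 16, BC107364 with 15, Gtf2ird1 and Klf9 with 14, Esrrb, Tbx3 and Plpp3 with 13, and Ahnak with 12, counted at the nearest gene end within 100 kb. The gene and 10 kb on each side held 10 KLF4 peaks for Gas8 and 0 for Rhou, counted by the centre of the peak. Gas8 and Rhou are neighbours on chromosome 8 (123518835 to 123536657 and 123653929 to 123663880) and had 0 and 2 iPSC H3K27ac peaks. Klf9 had 35, Tbx3 39 and Ahnak 43.

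The lists were all closer to gene ends than chance. Within 2 kb of an end of a protein-coding gene lay 44.7% (44.1 to 45.3) of 0 h bins, 44.5% (43.9 to 45.1) of 24 h bins, 36.3% (35.7 to 37.0) of KLF4 peaks and 28.2% (27.8 to 28.6) of iPSC H3K27ac peaks. The shifted lists gave at most 19.4%, 19.3%, 7.38% and 8.05% (circular-shift permutation test, p = 0.001 for each). Shares of bins and of peaks are not comparable with each other, since a bin is wider than most peaks.

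The fourth comparison set iPSCs against ESCs at 0 h. Of the iPSC H3K27ac peaks, 81.5% (81.2 to 81.8) lay in a 0 h bin with a value, and 73.6% (73.1 to 74.1) of the 0 h bins held an iPSC peak, against means of 11.2% and 11.1% in the shifts (circular-shift permutation test, p = 0.001). Only 0.40% of the iPSC peaks met a 0 h bin, and 0.83% of the 0 h bins an iPSC peak, when each had to cover 50% of the other, since peaks are narrower than bins. Genes with the largest excess of iPSC-only peaks were Rex2, 2410141K09Rik, Zfp640, Zfp970, Gm14410, LOC115486435, Gm9595, Gm19428, Zfp600 and LOC115488129, with 17 to 23 each, on chromosomes 2, 4 and 13. Rex2 (chromosome 4, 146973610 to 147060799) and 2410141K09Rik (chromosome 13, 66418114 to 66441118) had 23 each. None of the 78 bins that held these genes' 198 peaks was listed in ESCs at either time, so ESC acetylation there is unknown. Genes with the largest excess of 0 h bins without an iPSC peak over iPSC-only peaks included Grik3, Ror2, Usp9x and Epb41l4a with 8 each. Akr1d1, Ddah1, Diaph2, Gpbp1, Lamc1 and Lifr, the receptor for leukaemia inhibitory factor (LIF), had 7 each. Plpp3 also had 7, and was left out by the cut at 10 genes. These bins are 10 kb wide and carried no iPSC peak.

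Of the 15 gene lists, naive pluripotency genes had the lowest median 24 h over 0 h H3K27ac value relative to all bins. Their median relative value was -0.18 over 20 measured genes, with 16 below 0, at percentile 0.07 of 10000 random lists of equal level. It was the only list past the threshold after correction over 15 lists. By KLF4 peaks, its leading members were Esrrb (-0.06), Tbx3 (-0.22), Tfcp2l1 (-0.17) and Klf4 (-0.05). The list no longer passed when random lists also had equal numbers of KLF4 peaks (percentile 0.38, median -0.18), with 25 kb flanks (0.25, median -0.16) or with 1 bin per run of equal values (1.11, median -0.12). In each of these 3 settings its median still lay below the central 95% of random lists. The random lists were added after the data had been seen, describe these libraries and give no replicate error.

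Shared pluripotency genes had a median of -0.05 (percentile 19.3), with 14 of 19 below 0, among them Mycn (-0.05) and Etv5 (-0.04), while Jarid2 was at 0.03. Etv5 and Jarid2 changed sign under other choices of bins or flanks, as did Nodal, Tcf7l1, Wapl, Tfap2a, Gsc and Cdk1 among the genes named next. Primed or formative genes had a median of -0.07 (percentile 11.6, 6 of 11 below 0), with Foxd3 at -0.82, Otx2 at -0.32 and Nodal at -0.07. The KLF and SP family had a median of -0.06 (percentile 8.85, 12 of 18 below 0), with Klf10 at -0.67, Klf9 at -0.08 and Klf13 at 0.05. LIF and STAT3 response genes had a median of 0.03 (percentile 58.7, 6 of 13 below 0), with Pim1 at -0.19, Bcl3 at -0.12, Socs3 at 0.10 and Fos at 0.44. The list named Wnt and beta-catenin targets had a median of -0.08 (percentile 11.3, 6 of 9 below 0), with Ccnd1 at -0.34, Ctnnb1 at -0.10 and Tcf7l1 at -0.02. Its 3 members above 0 were Lef1 (1.02) and Znrf3 (0.70), from 1 bin each, and Tcf7 (0.15). Architectural and Mediator genes, which encode CTCF, cohesin and coactivator proteins, had a median of 0.08 (percentile 85.1), with 15 of 18 above 0, among them Ep300 (0.14), Wapl (0.07), Yy1 (0.05) and Pds5b (0.06, from 1 bin).

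Trophectoderm genes had a median of -0.12 (percentile 6.26, 5 of 8 below 0), with Tead4 at -0.25, Tfap2a at -0.15, Tfap2c at 0.11 and Krt8 at -0.18 from 1 bin. The highest value around Krt8 was 3.09 at 0 h and 5.38 at 24 h, in a bin without a 0 h value. Primitive endoderm genes had -0.07 (percentile 23.4, 3 of 5 below 0), with Sparc at -0.39 and Lamb1 at 0.20 from 1 bin. Mesendoderm genes had 0.07 (percentile 63.0, 1 of 4 below 0), with Gsc at 0.01 from 1 bin, and neuroectoderm genes -0.06 (percentile 30.6, 3 of 5 below 0), with Neurog1 at -0.06 and Pax7 at -0.33 from 1 bin. Fibroblast genes, markers of the feeder cells, had -0.04 (percentile 29.6, 3 of 6 below 0), with Fn1 at -0.12, Loxl1 at 0.04 and Vim at 1.06 from 1 bin. Glycolysis genes had 0.05 (percentile 77.6, 6 of 15 below 0), with Slc2a3 at -0.10 and Hk1 at 0.12. Cell cycle genes had 0.07 (percentile 82.9, 7 of 17 below 0), with Cdk1 at -0.17 and Rb1 at 0.16. Housekeeping genes had 0.03 (percentile 73.5, 8 of 19 below 0), with Ywhaz at 0.15 and Actb at -0.01. The mean of a list had the opposite sign to its median for Wnt targets (0.04), trophectoderm (0.05), mesendoderm (-0.08) and fibroblast genes (0.15).

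**Figure D4:**
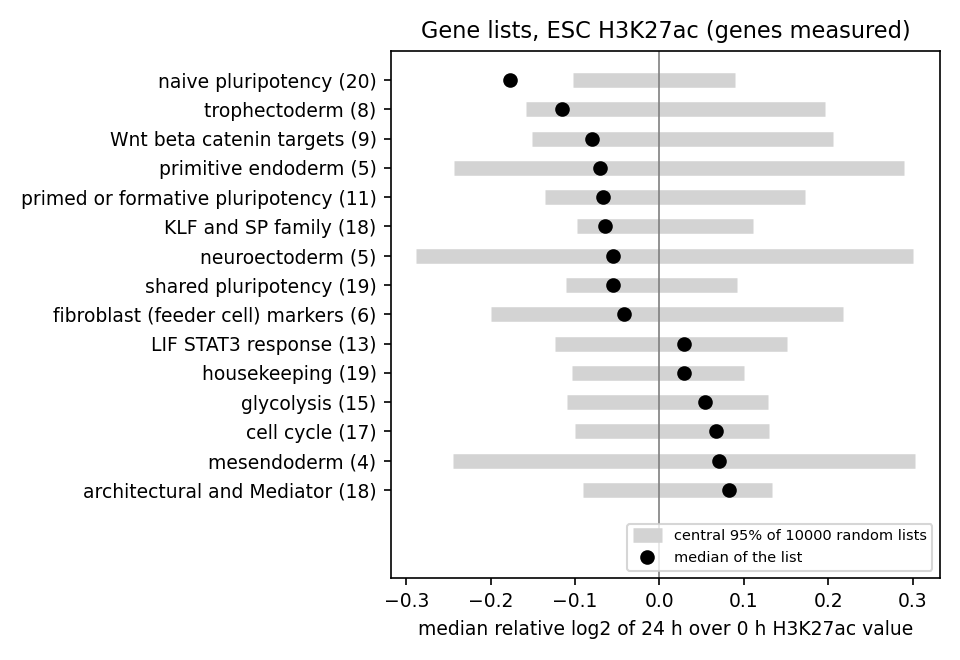
Median relative log2 of the 24 h over the 0 h ESC H3K27ac value (horizontal axis) for 15 gene lists, with the number of genes measured in brackets. Points are list medians and grey bars the central 95% of 10000 random lists, and naive pluripotency at -0.18 is the only point outside its bar.

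The test fixed before the data were examined counted genes with a bin or peak of each class. None of its 210 two-sided Fisher exact tests had an adjusted p under 0.05 (Benjamini-Hochberg over lists, classes and positions), 32 had an unadjusted p under 0.05, and the lowest adjusted p was 0.071. KLF4 peaks were assigned to 19 of 20 naive genes, against 66.7% of 10946 other genes (Fisher exact test, adjusted p = 0.11). The adjusted p was also 0.11 for 18 of 19 shared pluripotency genes, 18 of 19 cell cycle genes and 13 of 13 LIF and STAT3 response genes by the same Fisher exact test. At a gene end, KLF4 peaks lay at 12 of 13 LIF and STAT3 response genes, against 47.6% of the others (Fisher exact test, adjusted p = 0.071). For naive genes it was 12 of 20, against 47.6% (Fisher exact test, adjusted p = 0.71). KLF4 peaks were assigned to 21 of 22 KLF and SP genes (Fisher exact test, adjusted p = 0.074). A 24 h-only bin was assigned to 9 of 17 architectural and Mediator genes, against 19.5% of the others (Fisher exact test, adjusted p = 0.074). At a gene end such a bin lay at 3 of 17, against 9.24% of the others (Fisher exact test, adjusted p = 0.53). Neuroectoderm genes had an iPSC H3K27ac peak at a gene end in 0 of 6 cases, against 69.8% of the others (Fisher exact test, adjusted p = 0.071). By nearest gene, however, an iPSC H3K27ac peak was assigned to 6 of 6, against 85.9% of the others. Only 6 of the 16 listed neuroectoderm genes had an ESC bin assigned and entered the test.

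The largest stitched H3K27ac domains nearly all held KLF4. Of the 500 largest clusters, 99.2% at 0 h, 98.6% at 24 h and 98.2% in iPSCs contained a KLF4 peak, against 58.7%, 55.5% and 34.1% of the smaller ones. Large clusters have more room for a peak, and per 10 kb covered the 0 h clusters held 0.53 KLF4 peaks in the top 500 and 0.47 in the rest. In iPSCs the number per 10 kb covered was 2.17 in the top 500 and 3.08 in the rest. These counts include KLF4 peaks in the gaps between joined pieces, so they are not densities in acetylated sequence. Per 10 kb of span, gaps included, the top 500 held 0.47 at 0 h and 0.97 in iPSCs. The span value of the rest was not computed. The 5 largest iPSC clusters included those at Cd9, Trip12 and Fbxo36, Esrrb (chromosome 12, 86454387 to 86523575) and Macf1, with 11, 6, 11 and 5 KLF4 peaks. The largest 0 h clusters spanned the gene-dense regions of Ahnak (chromosome 19, 8690001 to 9110000, 32 KLF4 peaks), Bax (chromosome 7, 45300001 to 45750000, 30 KLF4 peaks) and the Ifitm genes (chromosome 7, 140820001 to 141260000, 25 KLF4 peaks), then Akr1d1 with Trim24, and Timeless with Stat2. At 24 h the largest lay at the Ifitm genes, Trim24, Timeless with Stat2, Aqp3 and Akt2. Of the 500 largest 0 h clusters, 406 overlapped one of the 500 largest at 24 h.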

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

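The tests on the mark columns, and the other tests here except the comparison with acetylated sites lacking KLF4 and the score test at equal change in value, were chosen after the values had been seen.

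Signals appeared in 4 of the 5 mark columns of the ESC lists, which the comparisons did not use except to leave out marked bins in 1 alternative. Bins marked in column 6 held a KLF4 peak in 68.1% of 467 bins, against 24.0% of other bins, and touched 153 genes, 9 of them naive genes, among them Esrrb, Nanog and Tbx3. Bins marked in column 9 held one in 81.2% of 303 bins and touched 181 genes, with Fbxo15 and Zfp42 as the naive ones. Bins marked in column 7 held one in 44.3% of 5636 bins and touched 2773 genes, 11 of them naive, and in column 5 in 40.7% of 1444 bins, with 542 genes and no naive one. The median relative H3K27ac value of marked bins was 0.01 in column 5, -0.10 in column 6, -0.04 in column 7, -0.01 in column 8 and -0.18 in column 9. Column 8 did not differ, with 24.8% against 24.4% (Fisher exact test, p = 0.67). Marked bins were also more acetylated in the columns with more KLF4. In column 6, 96.6% of marked and 53.8% of other bins had a value, with medians of 8.68 and 4.61. In column 9 these were 100% and 53.9%, with medians of 9.81 and 4.62. In column 8, 54.3% and 54.2% had a value. Neither the KLF4 shares nor the relative values of marked bins are adjusted for this level.

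The larger relative drop of H3K27ac at bins with an iPSC KLF4 peak was weighed first. Compression of high values is argued against only as the whole cause. The difference was -0.18 log2 without groups, -0.17 within groups of equal level and -0.11 within groups of equal 0 h value. The second of these is the value reported above rather than a separate test. The third leaves room for a part that follows from the 0 h level. A drop common to all acetylated iPSC sites is argued against as the whole cause, because bins with an iPSC H3K27ac peak and no KLF4 peak differed from bins with neither by -0.033 (SE 0.009). Peak width was not matched. iPSC H3K27ac peaks without KLF4 had median widths of 405 bp near and 329 bp away from gene ends, against 839 and 895 bp with KLF4. A drop that grows with the width of iPSC peaks is therefore not addressed. Loss of the KLF factors may underlie the pattern, but with 1 list per time it cannot be told apart from a difference between libraries or an effect of doxycycline.

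The smaller 24 h share of the bin score in KLF4 bins may follow from the H3K27ac value. A lower total at 24 h that scaled all bins in proportion would lower bins with and without KLF4 alike. That is argued against by a difference of -2.62 percentage points in the summed score, taken without groups. A loss that depends on the score level is not addressed by this value. In bins valued at both times the difference was -2.19 (SE 0.20), and within groups of equal change in value it was -0.67 (SE 0.15). That difference lies within the bound of 1 point set before it was seen, but remains below 0, and grouping on the change in value does not separate a cause from a consequence. A loss of KLF factors stays open as the source of both, untested for the same reason.

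The iPSC-only peaks around Rex2, Zfp640, Zfp970, Zfp600 and 6 other genes lay in 78 bins, of which 0% were listed in ESCs at either time. Bins left out of the ESC lists stay open as a source, because genes were picked for peaks outside valued 0 h bins, and only 17.5% of the 7584 other bins with such peaks were listed. Whether reads shared between near-identical gene copies produced these peaks was not tested, as no genome sequence was used. No biological explanation was tested.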

How the results depend on the processing

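The alternatives for the value difference, the score difference, the bins valued at 1 time only, the naive list, all listed bins, bins listed without a value and single genes were chosen after seeing the data. No paired analysis was possible because each group has 1 list and no column carries a replicate. For the same reason leaving out each replicate could not be done, motifs and 50% overlap between bins of 1 grid (also for the gene lists) were not run, and unknown depth limits every list. The causes of the changes below were not tested.

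The odds ratio for 0 h-only bins turned from 0.79 to 1.15 with value deciles, 1.07 with no 24 h bin within 1 kb and 1.13 above the median value of each H3K27ac list, and stayed between 0.59 and 0.82 in the other 7 alternatives. For 24 h-only bins it stayed between 0.21 and 0.37. Where both lists were cut at their medians or to equal length, a bin cut from the other list counted as absent there. The value difference at KLF4 bins stayed between -0.23 and -0.11, the score difference between -4.83 and -2.19, and the odds ratio of bins valued at 1 time only between 2.39 and 3.71.

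The share of 0 h bins with a 24 h value (84.8%) was 91.5% within 1 kb, 83.8% merged, 76.8% above the median of each list and 85.9% at equal length. KLF4 peaks in H3K27ac (48.7%) were 4.46% at 50% overlap, where widths limit the share, 58.7% within 1 kb, 53.1% above the median width and 38.1% at equal length. iPSC peaks in 0 h bins (81.5%) were 0.40% at 50% overlap, since peaks are narrower than bins, 82.1% within 1 kb, 74.7% merged, 63.9% above the medians, 81.9% on autosomes and 83.9% at equal length.

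The gene-end shares at 1 kb, 5 kb, ends of all genes and above the median of a list were 41.5%, 52.3%, 57.8% and 49.3% at 0 h, 41.2%, 52.1%, 57.5% and 48.9% at 24 h, 30.9%, 45.8%, 45.1% and 42.2% for KLF4, and 22.7%, 39.6%, 36.4% and 33.2% for iPSC H3K27ac. Clusters with KLF4 were 100% at 20 kb and 100% in the top 200 at 0 h, 99.6% and 100% at 24 h, and 95% at 5 kb and 99.4% at 20 kb in iPSCs. The planned gene-list test made 0 calls within 50 kb or 250 kb and 1 above the median of each list, KLF4 peaks at 17 of 18 shared pluripotency genes (Fisher exact test, adjusted p = 0.038). The naive list lay at percentile 0.25 with 25 kb flanks, 1.11 with 1 bin per run of equal values and 0.38 when matched on KLF4 peaks, no longer past the corrected threshold, although its median was -0.16, -0.12 and -0.18, below the central 95% of random lists in each. It lay at 0.05 to 0.11 in the other 4. Of 228 single genes, 44 changed sign in at least 1 of 4 alternatives, none with a main value larger than 0.31 in size.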

Other observations

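The genes with the largest differences in bin score between the times were ranked after the data had been seen and without a test. The summed score around Dlgap1 (chromosome 17, 69969073 to 70821413) was 212 at 0 h and 156 at 24 h, around Klf8, another KLF gene, 99 and 46 with a relative H3K27ac value of -0.61, and around Pakap 99 and 54. It was 277 and 234 around Sgms1, and 119 and 80 around Lrp5, a Wnt co-receptor gene with no KLF4 peak within 10 kb. In the other direction it was 76 and 143 around Arhgef3 (chromosome 14, 27114461 to 27403916), 120 and 169 around Pibf1, which lies next to Klf5 on chromosome 14 and had a relative H3K27ac value of 0.51, and 26 and 66 around Pacsin2. For Chst11 and Slc22a23, named above for H3K27ac, it was 14 and 50, and 45 and 77.

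A hypothesis formed from the data is that the bin score counts links between bins of one chromosome, as a chromatin contact assay would give. Each link would then add 1 to both of its bins, so an odd chromosome sum would argue against it, and 40 of the 40 chromosome sums in both lists were even. The even sums prompted the hypothesis, so they lend it no support, and it stays open because the meaning of the column is not given in the sources used here.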
